A study of Caenorhabditis elegans with 2 samples.

How the data were processed

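The data are chromatin immunoprecipitation sequencing (ChIP-seq) peak lists for HLH-8, the Caenorhabditis elegans Twist-family basic helix-loop-helix factor. Per the labels, hermaphrodite late embryos of strain OP63, which carries a transgene for HLH-8 with a C-terminal GFP-FLAG tag, were collected 3.5 hours after synchronization by bleaching. Per the labels' descriptions, the chromatin was sonicated with a microtip and precipitated with an antibody against GFP, in 2 biological replicates that form 1 group. An untagged strain and the control libraries were not analysed here.

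Per the deposited file inventories, each replicate has a list of candidate peaks, made from its alignments and a control, and the alignments of both replicates together have a pooled candidate list. These lists deliberately hold peaks together with background, as input for an irreproducible discovery rate (IDR) step, whose result is the deposited optimal list. All lists exist for the genome builds ce11 and ce10, per the file inventories, which makes 8 lists. The aligner and the peak caller are not given in the sources used here. The signal values of the peaks, in column 7, are the authors' own deposited caller values, and whether they were scaled for depth is not given in the sources used here. The -log10 q values in column 9 are likewise deposited by the authors. They reached the same ceiling for all 1120 optimal peaks of ce11 and for 1846 pooled candidates, so ranks were taken from the signal. Column 10 of the deposited lists gives the summit position.

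Read depth is unknown, because no read counts were used here, so no floor or counting interval could be given for a signal value. Intervals on shares of peaks or genes are exact 95% binomial intervals over sites, which are not independent replicates. The signal unit is arbitrary, and a value was compared only within its list or between the replicates at the same site.

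The main results use ce11. Peaks were set against the Ensembl release 115 annotation and the RefSeq sequence of the same assembly, and coordinates are 1-based. Mitochondrial protein-coding genes took their names from the RefSeq annotation by position. The ce10 lists served only for comparisons within that build, and no coordinate was converted. Calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots used matplotlib 3.10.9.

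Choices below were made before the data were examined unless stated otherwise. Replicates were compared through their 1120 strongest candidates, a summit within 200 bp counting as shared, with chance from 1000 circular shifts within chromosomes. Signals were compared across optimal peaks matched in both replicates, with permutation tests of 100000 resamples. Promoter peaks had a summit from 500 bp upstream to 200 bp downstream of the 5′ end of a protein-coding transcript. Optimal peaks were set against the 12952 weakest of the 25904 pooled candidates, called weak candidates here, with two-sided Fisher's exact tests. The chromosomes, the 10 classes of E-box (CANNTG), the 2080 distinct 6-mers and the 18 gene lists were 4 separate families with Benjamini-Hochberg adjustment and a threshold of 0.05. The 7 annotation classes were a further family, added after the data had been seen. E-boxes were counted within 50 bp of summits and compared with windows 500 bp to either side by exact McNemar tests, of which the larger p is given. Where several isoforms or genes overlap, a peak was counted for each window it fell in. A gene had a peak when an optimal summit lay from 2000 bp upstream to 500 bp downstream of its 5′ end, over 19973 nuclear protein-coding genes. Signal within 20 kb of hlh-8 and of unc-119, a marker often used in such transgenes, was compared with the median over genes of the same chromosome.

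The genes named were fixed by rule. They are the genes whose window holds, or else the nearest gene to, each of the 20 strongest optimal peaks, all members of the lists of HLH-8 targets and M lineage regulators, up to 3 members of every other list with the strongest optimal peak, and the transgene loci hlh-8 and unc-119. The lists cover HLH-8 targets, M lineage regulators, body wall muscle, pharyngeal muscle, intestine, epidermis and cuticle, neurons, germline, Notch, FGF and Ras, TGF-beta and Wnt signalling, Hox genes, the ceh, hlh and nhr families, ribosomal proteins and heat shock proteins.

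The tests were tried on simulated data. Of 10 6-mers planted in simulated windows 10 were recovered among 2080, and 0 were called with nothing planted. These windows were taken away from the summits, so the test does not cover the difference in GC content between summits and flanks given below. A list of 40 genes raised to a share of 30% was called in 93 of 100 simulated sets over 19973 genes, with 5 calls of other lists over all sets. Lists sharing members with the raised one were not counted among those calls. Genes were drawn independently there, whereas in the data 733 optimal summits gave 1083 genes a peak, so neighbouring genes can share one. The simulation does not cover that dependence, and the p values of the gene lists may be too small. For the replicate overlap, 72.9% of 1120 summits were made to be shared and 73.5% were measured. The shared summits were placed closer than the 200 bp limit, so their recovery was fixed in advance and checks only the counting. For the promoter share, 6 of 100 random draws of 1120 peaks fell under the threshold. Alternatives for distances, windows, backgrounds, peak thresholds, build and left-out replicates were tried, and others were added after the data had been seen. Where a replicate was left out, the 1120 strongest candidates of the other replicate stood in for the optimal peaks, without an IDR step. Comparisons with weak candidates then still used those of the pooled list, which draws on both replicates.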

Results

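HLH-8 binding was profiled in 1 group of 2 biological replicates, whole late embryos carrying tagged HLH-8. The ce11 candidate lists held 24268 peaks in replicate 1, 23945 in replicate 2 and 25904 in the pooled data, and the optimal list held 1120 peaks. All 1120 optimal peaks were the 1120 strongest peaks of the pooled list, 4.32% of it, with deposited signals from 57.4 to 1132. The ce10 optimal list was longer, at 1631 peaks. With no second condition, the comparisons are between replicates, between strong and weak sites, and between gene groups.

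The strongest site of the genome lay on chromosome III at 8043703 to 8044211 in ce11, between genes, in the windows of spcs-3, K12H4.5 and K12H4.6. Its pooled signal was 1132, and the replicates had a mean signal of 565 ± 25.2 (SD, n = 2). Of the 20 strongest peaks, 10 were nuclear and 10 lay on the mitochondrial genome, in or beside ND1, ND2, ND4, ND5, ATP6, COX1, COX2, COX3 and CYTB. The next nuclear site, at 3499844 to 3500271 on chromosome III, had a signal of 535.7 in an intron of M01F1.8 and in the window of M01F1.9. The others had signals from 271 to 317. They lay beside ears-2 and uncp-18, beside eel-1, which encodes a HECT-type ubiquitin ligase, beside atx-2, the ataxin-2 homologue, with ecps-1, beside W03C9.2, where a tRNA or snoRNA gene is also near, and beside lin-35, the retinoblastoma homologue, with vps-51. A site 4965 bp from nas-30 lay between genes, a site within ppfr-1 was intronic, and the remaining one was intronic in hlh-8 itself.

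Replicates shared most of their strongest sites. Of the 1120 strongest candidates of replicate 1, 68.0% had a summit within 200 bp among the 1120 strongest of replicate 2, and 67.4% held in the other direction. Circular shifts gave a mean of 1.16% and 1.20%, and the p of 0.001 is the smallest that 1000 shifts can give. Among candidates ranked 10001 to 20000, 21.1% of those of replicate 1 were shared with the 20000 strongest of replicate 2. Chance was not computed for so many peaks, where it is higher, so that share does not measure agreement. Across the 1117 optimal peaks matched in both replicates, signals correlated with a Spearman rho of 0.514 and a Pearson r of 0.639 on the log2 scale (permutation p = 1e-05 for each, the smallest that 100000 resamples can give). Without the 2 sites farthest from the median of replicate 1, r was 0.619. The correlation is across sites, which are not independent replicates, and the sites had been selected on a pooled signal whose median ratio to the sum of the replicate signals was 1.00, which narrows their range. At matched sites the log2 ratio of replicate 2 to replicate 1 had a median of 0.19 and an SD of 0.55.

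**Figure D1:**
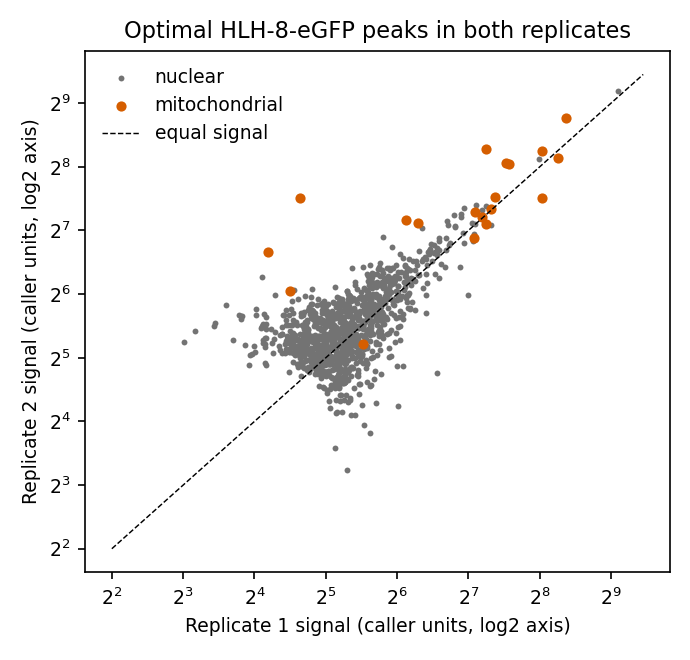
Signal of optimal peaks in replicate 1 (x axis) and replicate 2 (y axis), in the caller's units on log2 axes, with 1 point for each of the 1117 matched peaks and a dashed line at equal signal. Nuclear peaks are grey and mitochondrial peaks orange, and rho over all points was 0.514.

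Optimal peaks were concentrated at the promoters of protein-coding genes. Of 1120 summits, 524 (46.8%, exact 95% interval 43.8 to 49.8) lay in a promoter window, against 20.2% of the weak candidates (odds ratio 3.47, Fisher's exact p = 6.64e-80). Circular shifts gave a mean of 16.8% and a maximum of 19.8%. Summits of nuclear optimal peaks were a median of 526.5 bp from the nearest protein-coding 5′ end, against 1209 bp for weak candidates. When each peak was given 1 class, exons of protein-coding genes outside promoters held 1.79% of optimal peaks and 24.3% of weak candidates (Fisher's exact adjusted p = 4.49e-97), and introns held 10.8% and 28.6% (adjusted p = 9.77e-44). Intergenic sites held 28.7% and 26.2%, which did not pass the test (exact adjusted p = 0.0715).

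The X chromosome held 230 optimal peaks, 20.5% of the list against 16.9% of weak candidates (odds ratio 1.27, Fisher's exact test, Benjamini-Hochberg adjusted p = 0.00675 over 7 chromosomes). Chromosome V held fewer, 13.9% against 17.4% (odds ratio 0.768, exact adjusted p = 0.00675), and chromosomes I, II, III and IV did not pass the test. The excess on X did not hold for the stronger 560 optimal peaks, with an odds ratio of 0.956. It was not past the threshold without the peaks near tRNA and snoRNA genes, at an odds ratio of 1.09, or without replicate 1, at 1.16. Over the alternatives the exact adjusted p ranged from 0.00106 to 0.864.

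Some classes of E-box, the CANNTG sites that basic helix-loop-helix dimers bind, were enriched at the summits of the optimal list as a whole. Among the 10 nuclear sites of the 20 strongest peaks, only those within ppfr-1 (CACATG and CAGATG) and beside atx-2 (CAAGTG) held any class within 50 bp. Among the stronger 560 peaks the odds ratio against flanks was 3.67 for CAGATG and 3.08 for CACATG, against 4.68 and 3.85 over all 1120. CATATG, known from HLH-8 target promoters, occurred within 50 bp of 45 summits (4.02%, exact 95% interval 2.95 to 5.34), against 1.74% of flanking windows (exact McNemar adjusted p = 0.0118 over 10 classes) and 1.78% of weak candidates (Fisher's exact adjusted p = 1.11e-05). More sites held CAGATG, at 14.3% of summits and 3.44% of flanks (4.16 times, exact adjusted p = 5.02e-15), and CACATG, at 11.3% and 3.21% (3.53 times, adjusted p = 1.37e-10). CAGCTG was at 5.71% and 2.01% (exact adjusted p = 0.000209), and CAAGTG at 6.43% and 3.62% (adjusted p = 0.00964). CAAATG, CAACTG, CAATTG and CACCTG passed neither test. CACGTG, at 3.39%, did not pass against flanks (2.05%, exact McNemar adjusted p = 0.206) but did against weak candidates (2.13%, Fisher's exact adjusted p = 0.0181). For CAGCTG, CAAGTG and CACGTG no GC-matched value is given, so whether their excess goes beyond the GC difference given below is not shown. Against 1120 weak candidates matched on GC content, whose CATATG share was 2.23%, the CATATG share did not pass (exact adjusted p = 0.068), with fewer background windows and a higher background share, while the flank test is the same there. The matched candidates were drawn at random only once, so that p, near the threshold, could differ in another draw. The CATATG share also did not pass against flanks with windows of 100 bp to either side (6.61% and 3.79%), among the stronger 560 peaks, where fewer peaks entered (4.46% and 1.79%), and without replicate 2 (3.04% and 1.70%). Over the alternatives the exact McNemar adjusted p against flanks ranged from 0.0102 to 0.122. The Fisher's exact adjusted p against weak candidates ranged from 7.33e-07 to 0.068, and only with GC matching did it not pass.

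**Figure D2:**
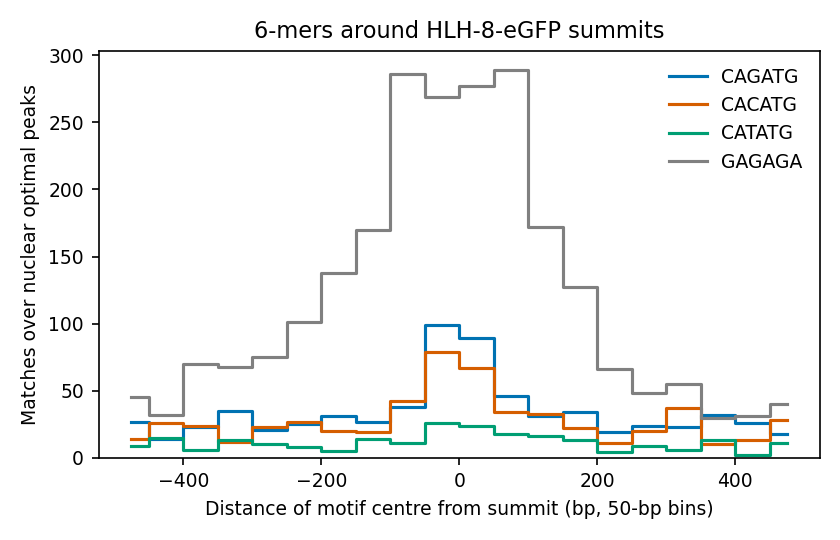
Number of matches of 4 6-mers (y axis) in 50-bp bins of distance from the summit in bp (x axis), over 1100 nuclear optimal peaks. CAGATG rose to 99 and CACATG to 79 matches in the 50 bp before the summit, CATATG to 26, while GAGAGA was spread more widely and reached 289.

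Over all 2080 6-mers, 676 were more frequent near optimal summits than in flanks and 468 less frequent. The leading ones were GAGAGA, in 25.6% of summit windows and 5.67% of flanks (odds ratio 5.73, Fisher's exact adjusted p = 5.53e-55), AGAGAG, CGAGAG and ACGCAG. Unlike the McNemar tests of E-boxes, these tests ignored the pairing of each summit with its own flanks. Summit windows were richer in GC, at a mean of 48.0% ± 8.35 (SD over 1120 windows) against 35.5% ± 8.77 in flanks and 37.8% ± 10.5 in weak candidates. Against all weak candidates, 636 6-mers were more frequent and 467 less frequent. Against GC-matched weak candidates, with fewer background windows from that random draw, 185 6-mers were more frequent and 216 less frequent, so the balance between the directions turned. In that comparison CAGATG had an odds ratio of 2.89 (Fisher's exact adjusted p = 3.33e-10), CACATG of 3.55 (adjusted p = 1.62e-10) and GAGAGA of 3.37 (adjusted p = 1.54e-21).

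Among the 5 known HLH-8 targets, 2 had an optimal peak in their window, against 5.41% of other genes, which did not pass the correction over lists (Fisher's exact p = 0.0263, adjusted p = 0.0863). They were mls-1 and hlh-8 itself, where transgene copies could not be separated from binding. At mls-1, a T-box gene of uterine muscle, a peak lay 117 bp upstream with a signal of 81.0 (replicates 40.2 ± 6.72, SD, n = 2) and a CAGATG within 50 bp. A summit in the 5′ UTR of hlh-8, 90 bp from the 5′ end, had a signal of 79.3 (39.5 ± 9.23, SD, n = 2) and a CATATG. The arg-1 promoter, which encodes a Notch ligand, had a candidate ranked 3494, 195 bp upstream, with CACATG and CAGATG. The egl-15 promoter, of the FGF receptor gene, had a candidate ranked 5290 with CATATG, 372 bp upstream. At ceh-24, an NK-2 class homeobox gene, the window held only a candidate ranked 14942, while an optimal peak lay 4482 bp upstream with a signal of 76.4 and none of the 10 E-box classes.

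Of 14 M lineage regulators, which pattern the postembryonic mesoblast, 2 had an optimal peak (14.3%, exact adjusted p = 0.392). ceh-20, a Pbx-family cofactor of Hox proteins, had a peak of signal 175.8 at 6978829 to 6979147 on chromosome III, 889 bp upstream (replicates 87.7 ± 44.9, SD, n = 2). The peak of mab-5, a Hox gene, ranked 1119 of the 1120. Candidates below the optimal list lay in the windows of hlh-2 (rank 2154), lin-12 (1911), unc-62 (2319), sma-9 (3156), hlh-1 (4305), eya-1 (8284), ceh-34 (10620), let-381 (22395) and fozi-1 (23295). No pooled candidate lay in the windows of mls-2, sem-2 and lin-39.

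Of the 18 lists, 3 had optimal peaks more often than other genes and 1 less often. Ribosomal protein genes had them at 18 of 76 genes (23.7% against 5.35%, odds ratio 5.49, Fisher's exact adjusted p = 1.61e-06), led by rpl-3 with a signal of 197.7, rps-24 with 186.9 and rpl-15 with 164.4. Body wall muscle genes had them at 9 of 40 (22.5%, odds ratio 5.10, exact adjusted p = 0.0021). They included pat-10, which encodes troponin C, with a peak of signal 117.2 in its 5′ UTR, mlc-3, a myosin light chain gene, with 82.4, and mup-2, which encodes troponin T, with 76.9. The mlc-3 summit lay 1103 bp upstream, in an intron of another protein-coding gene. CAGATG was near the pat-10 summit, and none of the E-box classes was near those of mlc-3 and mup-2. Wnt signalling genes had optimal peaks at 5 of 21 (23.8%, odds ratio 5.47, exact adjusted p = 0.0205), led by hmp-2, a beta-catenin, with 117.2, cwn-1, a Wnt ligand, with 79.0, and lin-17, a Frizzled receptor, with 61.8. The nhr nuclear receptor family had them at 4 of 269 genes (1.49%, odds ratio 0.261, exact adjusted p = 0.00975), the strongest being nhr-255, nhr-64 and nhr-1. The peak of nhr-255 lay beside a tRNA or snoRNA gene, and without such peaks the family had 3.

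These calls depended on the choices made. The odds ratios of the called lists stayed on the same side of 1 in every alternative, but came as near to it as 1.68 for Wnt signalling. Body wall muscle had 5 of 40 genes without replicate 1 (odds ratio 2.58, Fisher's exact adjusted p = 0.207) and 14 of 40 without replicate 2 (odds ratio 9.77), with the strongest candidates of the remaining replicate in place of optimal peaks. Against only the genes with a pooled candidate the odds ratio of body wall muscle was 2.70 (exact adjusted p = 0.102), and among the stronger 560 peaks it was 1.77 (adjusted p = 0.760). Wnt signalling did not pass with windows of 1000 bp upstream (odds ratio 3.99, exact adjusted p = 0.151), with the nearest 5′ end (4.36, 0.142), against genes with a candidate (3.49, 0.129), without replicate 1 (4.24, 0.112) or among the stronger peaks (1.68, 0.922). Ribosomal proteins did not pass with the nearest 5′ end (odds ratio 1.88, exact adjusted p = 0.303). The nhr family did not pass there (odds ratio 0.563), with the windows of 1000 bp (0.357) or against genes with a candidate (0.322, exact adjusted p = 0.102). Over all alternatives the exact adjusted p ranged from 1.18e-07 to 0.303 for ribosomal proteins, 1.39e-07 to 0.760 for body wall muscle, 0.00179 to 0.922 for Wnt signalling and 0.00566 to 0.303 for the nhr family.

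The other lists did not pass the test. No gene of pharyngeal muscle (0 of 11), intestine (0 of 24), epidermis and cuticle (0 of 30) or TGF-beta signalling (0 of 13) had an optimal peak, with exact 95% upper limits of 28.5%, 14.2%, 11.6% and 24.7%. Neuronal genes had a peak at unc-76 alone (1 of 32) and germline genes at mex-1 alone (1 of 30), where the signal was 246.0. That summit lay 898 bp from the mex-1 5′ end and also in the windows of rab-7 and W03C9.5, the nearest at 195 bp. With nearest 5′ ends the germline list had 0 of 30. Heat shock protein genes reached 4 of 22 (exact adjusted p = 0.0863), led by hsp-60, hsp-3 and hsp-1. The hlh family had 3 of 25, namely hlh-10, hlh-11 and hlh-8, the ceh family 2 of 63, ceh-20 and ceh-38, Notch signalling 2 of 17, sel-12 and sup-17, and Hox genes 1 of 6, mab-5. FGF and Ras signalling had 1 of 12, egl-17, whose peak lay beside a tRNA or snoRNA gene, and 0 without such peaks.

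**Figure D3:**
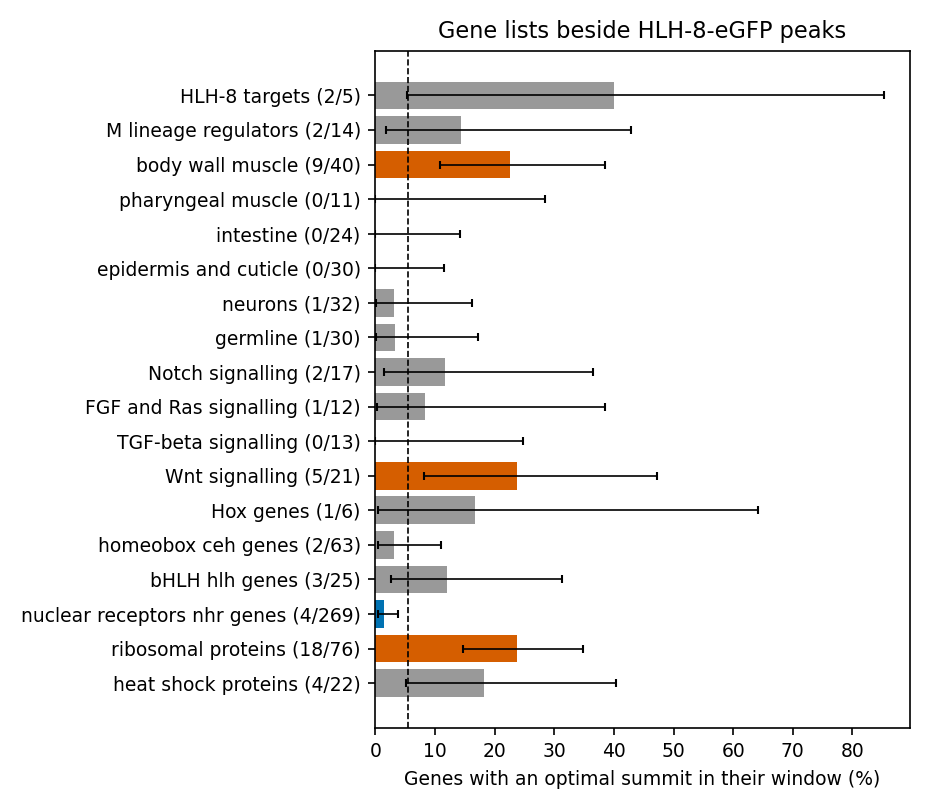
Share of genes with an optimal summit in their window in % (x axis) for each of the 18 gene lists (y axis, with gene counts), with exact 95% binomial intervals. The dashed line is the 5.42% of all 19973 genes, orange bars passed the test above it and the blue bar below it.

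The hlh-8 gene, on chromosome X at 8116457 to 8120351, held 4 pooled candidates, of which 3 were optimal peaks. The optimal summits 8118027 and 8118227 lay in the same region, so they are not separate sites. The strongest peak in the gene, at 8117832 to 8118235 in intron 2 of the transcript with 6 exons, ranked 19. It had a signal of 271.8 (replicates 137 ± 1.24, SD, n = 2) and none of the 10 E-box classes within 50 bp of its summit. Within 20 kb of hlh-8 the summed signal of 7 candidates was 551.8, which was 2.26 times the median over 2731 genes on X and at percentile 97.1. The 4 candidates inside the gene made up 464.4 of that sum, the signal outside it was at percentile 8.42 in the pooled list but 77.7 and 88.3 in the replicates, and within 10 kb the ratio was 3.85. Within 20 kb the ratio was 3.30 in each replicate, where 12 and 17 candidates were called. Around unc-119, on chromosome III, 16 candidates gave 1.11 times the median, at percentile 58.9. There the ratio was 1.36 in replicate 1 and 0.831 in replicate 2, and in the pooled list 0.822 within 10 kb and 0.937 within 40 kb. Untransformed worms were not analysed here, so copies added by the transgene could not be separated from binding.

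**Figure D4:**
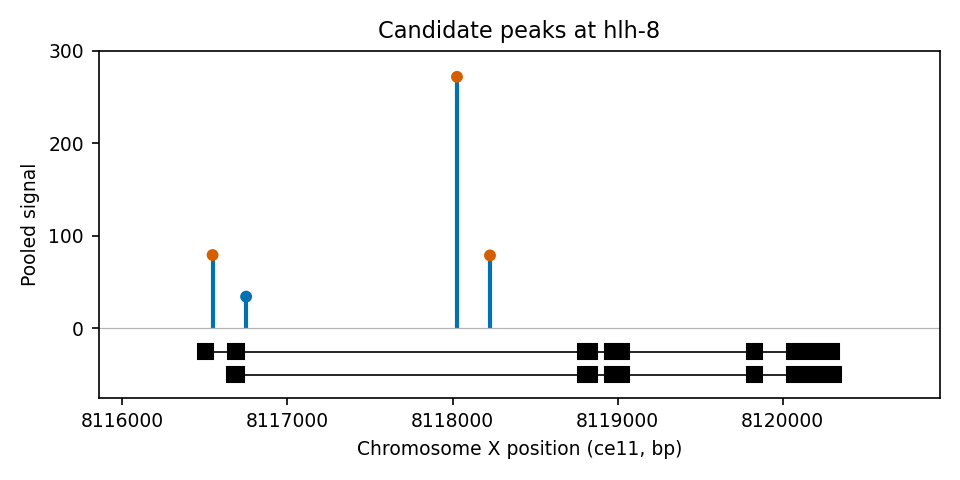
Pooled candidate peaks at hlh-8, with ce11 position on chromosome X in bp (x axis) and pooled signal in the caller's units (y axis), orange heads being optimal peaks and blue heads other candidates. Both annotated transcripts are drawn below with exons as boxes, and the summit of signal 271.8 lies in an intron.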

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

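Of the tests in this part only that of repeated words in tRNA genes was set out before its result was seen, and those of mitochondrial coverage, of E-boxes and of the hlh-8 flanks were chosen after. Binding to E-boxes was tested, but no biological difference between groups was, because the design has 1 group.

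A signal lay at mitochondrial, tRNA and snoRNA genes, which are in none of the gene lists. There were 20 optimal peaks on the mitochondrial genome, with a median signal of 277, where weak candidates had 0. Optimal peaks lay under 43.0% of the 13794 bp of that genome, while the highest share in any of 200384 nuclear windows of that length was 9.66%. That share restates the pattern, so whether many copies of mitochondrial DNA were left unbalanced by the control stays open. Binding to E-boxes stays open too, since 10.0% of the mitochondrial summits had CAGATG, CACATG or CATATG, which did not exceed the upper end of the central 95% of shifted positions, also 10.0%, while the exact 95% upper limit of 31.7% included the nuclear share of 26.6%.

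Nuclear tRNA genes lay within 200 bp of 96 optimal peaks (8.57%, against 0.556% of weak candidates, odds ratio 16.8, Fisher's exact p = 1.16e-61), and snoRNA genes of 48 (4.29% against 0.270%, odds ratio 16.5, p = 1.37e-31). With the bodies of these genes masked, 12.5% of the 144 summits had CAGATG, CACATG or CATATG, against 18.5% at other nuclear peaks under the same masks, a value inside the exact 95% interval of the first. Their own flanks had 12.2%, so no excess over flanks was seen, although 34.7% of the summit bases were masked, and E-box binding stays open. Reads shared between gene copies may contribute at tRNA genes, since 94.3% of their 36-bp words were repeated in the genome at the 102 tRNA genes with a peak and 84.5% at the 510 without (permutation p = 0.00253). The test took the genes as independent, although copies share words and can lie near the same peak, so its p may be too small. How reads matching several places were handled is not known, so the direction of such an effect is not fixed. That word length was assumed, and transcription of the multicopy genes was not measured.

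Around hlh-8, extra copies of the region from the transgene could raise signal beyond the gene. Outside the gene and within 20 kb, the summed pooled signal was at percentile 8.42 of genes on X, but at 77.7 in replicate 1 and 88.3 in replicate 2. Added copies and binding cannot be told apart, because the pooled and replicate lists went opposite ways and no untagged sample was analysed here.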

How the results depend on the processing

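Alternatives that left out mitochondrial peaks, left out peaks near tRNA or snoRNA genes, kept 1 summit per 500 bp or matched GC content were chosen after seeing the data. Of 62 alternatives over 8 results, 46 kept the direction and side of the threshold or, for the numbers of 6-mers and gene lists, a number within 1.5 times, which does not say that the same ones were called. With windows of 1000 bp Wnt signalling and the nhr family lost their calls, and with 5000 bp the HLH-8 targets gained one. All 7 alternatives for replicate overlap, all 6 for replicate correlation and all 8 for the promoter share kept direction and side. The X odds ratio turned to 0.956 among the stronger 560 peaks and was 1.09, past no threshold, without peaks near tRNA or snoRNA genes. With 1 replicate left out it ranged from 1.16 to 1.25. Against flanks, the CATATG share lost its call at 6.61% with windows of 100 bp, at 4.46% among the stronger peaks and at 3.04% without replicate 2. In these settings it kept its call against weak candidates (Fisher's exact adjusted p = 9.98e-05, 0.00027 and 0.014). Against GC-matched weak candidates it lost that call at 4.02%, while the flank test was unchanged. Without replicate 1 the share was 4.29%. Against all weak candidates 636 6-mers were more and 467 less frequent, and against the fewer GC-matched ones 185 and 216. The number of gene lists with more peaks than other genes was 1 with nearest 5′ ends, 1 against genes with a candidate and 1 among the stronger peaks, and from 1 to 3 with a replicate left out. The lower share of the nhr family kept its call among the stronger peaks and with either replicate left out. The hlh-8 signal ratio was 3.85 within 10 kb and 1.85 within 40 kb, and 3.30 in each replicate alone. Having no test, it counted as kept only if it moved by less than the SD between the replicates, which were nearly equal, so all 4 alternatives counted as moved although each stayed above 1. Fewer peaks entered the stricter setting, and for the rest the cause was not tested. Unknown read depth limits the ranks of weak candidates.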

Other observations

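Some optimal peaks lay outside the gene windows but near known targets. An optimal peak lay 3026 bp downstream of the mls-1 5′ end, beyond the gene, with a signal of 80.1 and CAGATG. Another lay 8520 bp downstream of the egl-15 5′ end, also beyond the gene, with a signal of 59.1 and CATATG. A stronger one lay at 15022 bp, in an intron of another protein-coding gene, with a signal of 96.9 and none of the E-box classes. These were chosen after their values were seen. With gene windows of 5000 bp upstream, 3 of the 5 HLH-8 targets had an optimal peak (Fisher's exact adjusted p = 0.0194), 1 of them hlh-8 itself, where transgene copies could not be separated from binding. This was the only 1 of 9 alternatives in which that list passed, and the exact adjusted p ranged up to 0.587 over them.

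A hypothesis, found and tested on the same data with tests chosen after the result was seen, is that paired E-boxes favour a fixed spacing. Near nuclear optimal summits, 11 of 68 adjacent pairs of CAGATG, CACATG or CATATG were 5 bp apart (16.2%, exact 95% interval 8.36 to 27.1), and the next most frequent spacing had 3 pairs. Flanks held 0 of 8 such pairs, too few to decide (Fisher's exact p = 0.594). A comparison added because of that set them against weak candidates, which held 0 of 77 (Fisher's exact p = 0.000151). The spacing was picked because it was the most frequent in the same pairs, which makes that p too small, so neither comparison decides whether a spacing is preferred.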
